A study of Bos taurus with 18 samples.

How the data were processed

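RNA from bovine blastocysts was extracted with a kit for very small samples, amplified in 2 rounds with T7 RNA polymerase and labelled with Cy3 and Cy5 by direct chemical coupling, per the labels' protocols. The 18 Agilent 2-colour arrays were deposited as scanner output, with intensities of each channel per spot, from Feature Extraction 10.5.1.1 or 10.7.3.1 per the file headers. Mean signals, local background medians and processed signals are intensity columns on a linear scale, per the file headers, and the deposited log10 ratio of Cy5 over Cy3 of each spot was not used for the tests. The authors also deposited a value table of 43794 probes that holds log2 ratios of Cy5 over Cy3. Its scale and direction were settled by comparison with the scanner values of the same arrays, its medians lay between -0.031 and 0.00019, and how the authors normalized it is not given in the sources used here.

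The 45212 spots of each array included 1417 control spots. Background was corrected with normexp (offset 50), and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 and R 4.3.3. Spots flagged as outliers, 0 to 186 per array, were left out, and no spot was saturated. Ratios were turned to the group over in vivo by the dyes in the labels, and the 2 dye-swapped arrays of a replicate were averaged, so that 9 replicate values per probe entered the fit. The turned ratios of the 2 arrays of a replicate correlated at 0.16 to 0.60 across tested probes. A probe was tested when it was well above background in at least 4 of the 6 channels of a group or 12 of the 18 in vivo channels. This left 16987 probes. The percentages of probes well above background are given with the results.

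All 9 replicates were fitted in one linear model with lmFit and eBayes (6 residual degrees of freedom, prior 3.53). The 3 comparisons with in vivo test the mean ratio against 0, the 3 between groups test differences of ratios, and the interaction is the IVP ratio minus the sum of the other two. All tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p under 0.05 over the tested probes. SE is that of the fit, and SD that of the 3 replicate values of a group. Because the spread is pooled over groups, a probe with widely spread values in 1 group can still pass. Whether the in vivo RNA is one pool or several samples is not in the labels. If it is one pool, a ratio against it leaves out the spread of the in vivo samples.

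The labels give the groups the same replicate numbers. Deviations from the group means correlated at 0.45 to 0.68 for all 9 pairs of same-numbered replicates of different groups. The numbers therefore pair the samples, on the evidence of the data. The 18 other pairs lay at -0.48 to -0.11. Deviations cancel out within a group, so these negative values follow largely from the positive ones and are not separate evidence. Fits with the replicate number as a block are therefore given beside the results. For differences between groups this block removes the variation that same-numbered samples share. For comparisons with in vivo it also takes the variation between the in vivo samples out of the error but not out of the mean, so those blocked counts are too high.

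Arrays were simulated from the real signals with 200 changed probes per group and variation shared by number. The 2 dye-swapped arrays of a simulated replicate had the same variation, unlike the real ones. The share of unchanged probes among calls depends on how many probes change, so it holds for these settings alone. For IVP against in vivo, 18.0% of the 1.5-fold, 74.0% of the 2-fold, 98.0% of the 3-fold and 96.0% of the 4-fold changes were recovered over 16987 probes, and 10.6% of 160 calls were unchanged probes. With the block, 52.1% of 382 calls were unchanged probes. For IVP against Vivo_morula 55.6% of 2-fold changes were recovered without the block and 90.9% with it, and unchanged probes made up 0 of 244 and 16 of 329 calls. For the interaction with the block, 16.0% of 518 calls were unchanged probes.

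The 6 slides each held 1 group in 1 dye orientation, with replicates 1 to 3 side by side. IVP and Vitro_morula were scanned together on 2 days, one per orientation, and all Vivo_morula arrays on another day. Slide was tried as a random block, and each orientation was fitted alone. The other alternatives changed the background correction, the normalization, the filter, the flags, the samples in the fit, the treatment of the in vivo channels and the threshold, left out each replicate in turn, and used the authors' table. The comparisons, the filter and all but 3 of these alternatives were fixed before the data were examined.

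Every probe carries an identifier in place of a gene name in the files used here, and 0 of 43795 had another name. The 27 gene lists fixed beforehand were therefore not tested, nor were gene-level means. The rule for named items had asked for gene symbols, and it was applied to probes instead. It takes the largest rises and falls past the threshold that go the same way on all 6 arrays, or, between groups, with all replicates of one group above all of the other in both dye orientations. For the interaction no condition on replicates was set. A probe also had to be well above background in at least 1 channel on each side, a condition added after the data were seen. The rule allowed more items, and at most 2 probes per direction are named because the identifiers carry no gene.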

Results

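Gene expression was measured in bovine blastocysts, the embryo stage with a fluid-filled cavity that follows the compacted morula. The series crosses the environment before the morula stage with the environment during blastocyst formation. In vivo blastocysts developed in the donor throughout, and IVP blastocysts developed in vitro throughout. Vitro_morula embryos were made in vitro, moved as morulae into recipient animals and flushed as blastocysts. Vivo_morula embryos developed in the donor up to the morula, were flushed and formed blastocysts in culture. Each of the 18 arrays carried RNA of 1 of these 3 groups in one dye and in vivo RNA in the other. Each group had 3 replicates, and each replicate was hybridised on 2 arrays with the dyes exchanged. The labels do not say whether the replicates came from separate animals or collections, so p-values measure the spread between these samples, which may be partly technical.

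The groups also differed in other ways that the labels record. In vivo and Vitro_morula blastocysts were collected on day 7 and staged by morphology, IVP blastocysts at 168 hours by fixed time. Vivo_morula samples carry day 6 and fixed time in their labels, while the design text gives day 7 for them. In vivo, Vitro_morula and Vivo_morula embryos were from Simmental heifers, and no breed is given for IVP. Of 43795 probes that were not controls, 16987 were bright enough to be tested. Between 27.4% and 48.0% of probes were well above background in the group channel of an array, and between 24.5% and 57.1% in the in vivo channel. Vitro_morula labelled with Cy5 was the dimmest, at 27.4% to 32.2%, against 33.4% to 45.5% for IVP and 41.4% to 44.8% for Vivo_morula in that dye. In Cy3 this did not hold: Vitro_morula had 32.1% to 48.0%, IVP 32.5% to 37.5% and Vivo_morula 33.7% to 38.0%. The number of arrays limits the precision. The files do not pair probes with genes, so results are given by probe identifier, and no probe is placed in the genome.

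Each group was first compared with in vivo blastocysts, which asks how far its transcript levels lay from those of embryos that stayed in the animal until collection. The plot of counts per comparison shows 3674 probes past the threshold for IVP, 4283 for Vitro_morula and 4586 for Vivo_morula. How near these counts lie depends on the processing: in the same order they were 1158, 2586 and 4137 with only the compared group in the fit, and 7041, 3562 and 5160 with median centring. The direct comparisons between groups called fewer probes when replicates were treated as unrelated. Counts with the replicate number as a block are given beside the counts. Against in vivo they overstate the differences, since in simulated data 52.1%, 53.5% and 53.6% of such calls in IVP, Vitro_morula and Vivo_morula were unchanged probes, against 10.6%, 4.85% and 9.49% without the block.

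**Figure D1:**
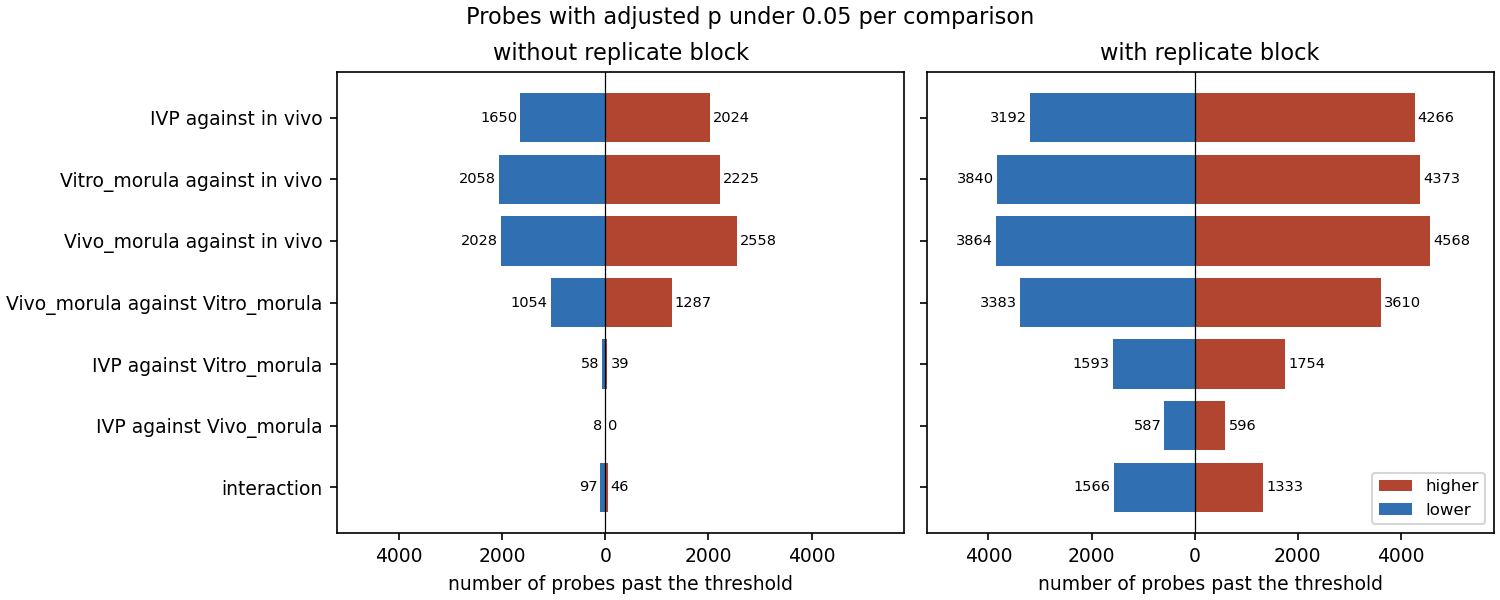
Number of probes (horizontal axis) with adjusted p under 0.05 in each of the 7 comparisons (vertical axis), higher to the right in red and lower to the left in blue, without and with the replicate number as a block. Without the block, IVP against Vivo_morula had 0 probes higher and 8 lower, and Vivo_morula against in vivo had 2558 higher and 2028 lower.

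In IVP blastocysts 2024 probes were higher and 1650 lower than in vivo, 21.6% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05, two-sided). At 123 of these calls 1 side was never well above background. The median change was 1.62-fold, 13 probes were at least 4-fold higher and 21 at least 4-fold lower. EMBV3_02417 rose by a log2 ratio of 3.62 ± 0.41 (SE; SD 1.1, n = 3; limma adjusted p = 0.0014), with in vivo RNA well above background on 1 of its 6 arrays, so that the size of this ratio is not exact. EMBV3_33905 rose by 2.89 ± 0.54 on the log2 scale (SD 1.1, n = 3; limma adjusted p = 0.0076), and without IVP replicate 3 this call was lost (limma adjusted p = 0.055). EMBV3_30571 fell by 2.99 (SE 0.54, SD 0.76, n = 3; limma adjusted p = 0.0068) and EMBV3_25141 fell by 2.97 (SE 0.18, SD 0.41, n = 3; limma adjusted p = 0.00046). All 4 moved in one direction on all 6 arrays. Their mean log2 ratios had the same sign in the other groups. In the order named, they were 3.24, 1.23, -1.39 and -2.13 in Vitro_morula, and 3.71, 2.54, -2.84 and -1.84 in Vivo_morula. The excess of higher calls turned with a 2-fold minimum (298 higher, 399 lower) and with only IVP in the fit (544 higher, 614 lower). The share of higher calls was 55.1% and became 91.8% of 7041 calls with median centring in place of loess, which moved the median log2 ratio of all tested probes from 0.03 to 0.37. The blocked fit called 7458 probes, 4266 higher and 3192 lower, without IVP replicate 2 the count was 1598, and without IVP replicate 3 it was 1228.

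In Vitro_morula blastocysts 2225 probes were higher and 2058 lower than in vivo, 25.2% of those tested (limma, adjusted p under 0.05). The median change was 1.60-fold, with 53 probes at least 4-fold higher and 9 at least 4-fold lower. Of the 53, 21 were above a log2 ratio of 3 in replicates 2 and 3 and below 1 in replicate 1. At 430 of all calls 1 side was never well above background. EMBV3_04607 had the largest rise under the rule for named probes, a mean log2 ratio of 4.03 ± 0.91 (SE; limma adjusted p = 0.014), and its 3 replicates stood at 0.08, 5.80 and 6.21. EMBV3_06488 rose by 3.84 ± 0.79 (SE; limma adjusted p = 0.0097), from replicates at 0.52, 5.33 and 5.66, with in vivo RNA well above background on 1 of its 6 arrays, so that the size of this ratio is not exact. Both calls were lost without Vitro_morula replicate 2 (limma adjusted p = 0.085 and 0.063) and without replicate 3 (limma adjusted p = 0.10 and 0.073). EMBV3_35188 fell by 3.28 (SE 0.46, SD 0.31, n = 3; limma adjusted p = 0.0027) and EMBV3_09661 fell by 2.73 (SE 0.39, SD 0.75, n = 3; limma adjusted p = 0.0028). EMBV3_35188 and EMBV3_09661 were also low in IVP, at -2.92 and -2.33, and in Vivo_morula, at -2.58 and -1.91. EMBV3_04607 stood at -0.10 in IVP and -0.001 in Vivo_morula, and EMBV3_06488 at 0.21 and 0.62. Neither of these probes was well above background in all 6 channels of any group, so ratios near 0 may come from dim channels rather than equal levels. The share of higher calls went from 51.9% to 62.5% with median centring. With only Vitro_morula in the fit, 1286 were higher and 1300 lower. The blocked fit called 8213, 4373 higher and 3840 lower, and the count without Vitro_morula replicates 1, 2 or 3 was 2765, 1899 and 1152.

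In Vivo_morula blastocysts 2558 probes were higher and 2028 lower than in vivo, 27.0% of those tested (limma, adjusted p under 0.05). The median change was 1.58-fold, with 20 probes at least 4-fold higher and 24 at least 4-fold lower, and at 159 calls 1 side was never well above background. EMBV3_02417, also the leading probe in IVP, rose by 3.71 ± 0.41 (SE; SD 0.42, n = 3; limma adjusted p = 0.0012), with in vivo RNA well above background on 1 of its 6 arrays, so that the size of this ratio is not exact. EMBV3_09809 rose by 3.66 ± 0.48 (SE; SD 0.48, n = 3; limma adjusted p = 0.0018). EMBV3_18825 fell by 3.76 (SE 1.0, SD 1.9, n = 3; limma adjusted p = 0.023), with the group's RNA well above background on 1 of 6 arrays, so that the size of this fall is not exact, and lost its call without Vivo_morula replicate 1 (limma adjusted p = 0.10) and without replicate 3 (limma adjusted p = 0.15). EMBV3_30571 fell by 2.84 (SE 0.54, SD 1.4, n = 3; limma adjusted p = 0.0063), and stood at limma adjusted p = 0.051 without Vivo_morula replicate 3. In IVP the mean log2 ratios of EMBV3_02417, EMBV3_09809, EMBV3_18825 and EMBV3_30571 were 3.62, 2.16, -3.44 and -2.99. In Vitro_morula they were 3.24, 1.43, -1.37 and -1.39. The share of higher calls went from 55.8% to 86.0% with median centring and to 70.3% with the processed signals. The blocked fit called 8432, 4568 higher and 3864 lower, and the count without Vivo_morula replicates 1, 2 or 3 was 1961, 2602 and 1399.

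The 2 dye orientations agreed poorly in these comparisons with in vivo. Log2 ratios from the arrays with the group in Cy5 and those with it in Cy3 correlated across probes at 0.23 for IVP, 0.40 for Vitro_morula and 0.36 for Vivo_morula, where probes are not independent replicates. In IVP 1669 probes passed in both orientations in the same direction and 936 in opposite directions. The same counts were 2122 and 732 for Vitro_morula and 2225 and 731 for Vivo_morula. Independent lists of these sizes would share 934 probes in the same direction for IVP, 837 for Vitro_morula and 899 for Vivo_morula. The share of higher calls with the group in Cy5 and in Cy3 was 45.6% and 62.9% for IVP, 41.5% and 62.6% for Vitro_morula, and 47.3% and 61.1% for Vivo_morula. The averages over both dyes cancel a dye effect that is equal in the 2 orientations.

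Vivo_morula and Vitro_morula passed through the 2 environments in opposite order, and comparing them directly asks whether the order mattered. Vivo_morula was higher at 1287 probes and lower at 1054 (limma, adjusted p under 0.05). EMBV3_12669 was 13.9-fold higher in Vivo_morula, with mean log2 ratios over in vivo of 2.58 ± 0.13 (SD, n = 3) there and -1.22 ± 0.23 in Vitro_morula (limma adjusted p = 0.00078). EMBV3_13552 was 11.1-fold higher (2.53 ± 0.20 against -0.94 ± 0.36, SD, n = 3; limma adjusted p = 0.0014). EMBV3_04866 was 8.46-fold lower in Vivo_morula (-1.66 ± 1.2 against 1.42 ± 1.6, SD, n = 3; limma adjusted p = 0.03) and EMBV3_29612 7.76-fold lower (-1.20 ± 0.36 against 1.76 ± 1.7, SD, n = 3; limma adjusted p = 0.022), the latter with Vivo_morula well above background on 2 of 6 arrays and a size that is not exact. Both of the latter calls were lost without Vitro_morula replicate 2 (limma adjusted p = 0.10 and 0.079) or 3 (limma adjusted p = 0.089 and 0.062), and without any 1 of the Vivo_morula replicates (limma adjusted p from 0.058 to 0.083). These losses came from fits without the replicate block. With the block and all replicates kept, EMBV3_04866 and EMBV3_29612 had a limma adjusted p of 0.0075 and 0.0035. The 2 dye orientations gave log2 differences that correlated at 0.88 across probes, and 600 probes passed in both with none opposite.

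With the replicate block 6993 probes differed between Vivo_morula and Vitro_morula, 3610 higher and 3383 lower. Without the block the count fell to 4 when Vitro_morula replicate 2 was left out, to 1008 without Vitro_morula replicate 3, and to 147, 559 and 648 without Vivo_morula replicates 1, 2 and 3. The share of higher calls went from 55.0% to 78.7% with median centring, and to 89.5% of 19 calls with the processed signals, and was 62.1% of 2388 calls with the groups in Cy5 and 42.1% of 876 in Cy3. All Vivo_morula arrays were scanned on a day of their own, so scan day and group cannot be told apart in comparisons of Vivo_morula with Vitro_morula or IVP.

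IVP and Vitro_morula shared in vitro development up to the morula and differed in the site of blastocyst formation. IVP was higher at 39 probes and lower at 58 (limma, adjusted p under 0.05), and at an unadjusted p under 0.05 the counts were 1739 and 1596. EMBV3_17159 was 6.56-fold higher in IVP (0.87 ± 0.42 against -1.85 ± 0.41, SD, n = 3; limma adjusted p = 0.037), with Vitro_morula well above background on 1 of 6 arrays, so that the size of this fold is not exact. EMBV3_19872 was 3.98-fold higher (1.29 ± 0.23 against -0.70 ± 0.43, SD, n = 3; limma adjusted p = 0.037). EMBV3_41934 was 4.53-fold lower (-1.56 ± 0.30 against 0.62 ± 0.12, SD, n = 3; limma adjusted p = 0.026) and EMBV3_30084 4.03-fold lower (-0.95 ± 0.54 against 1.06 ± 0.29, SD, n = 3; limma adjusted p = 0.041), the latter with IVP well above background on 3 of 6 arrays. No probe passed without Vitro_morula replicate 2, IVP replicate 2, IVP replicate 3 or Vivo_morula replicate 1, 1 passed without IVP replicate 1, and 339 without Vitro_morula replicate 1. With each of the 9 replicates left out in turn, EMBV3_17159 lost its call in 7 fits, EMBV3_19872 in 7, EMBV3_41934 in 4 and EMBV3_30084 in 8 (limma adjusted p from 0.05 to 0.15). These fits had no replicate block. With the block and all 9 replicates, the limma adjusted p of these probes was 1.5e-05, 0.0011, 0.00042 and 0.0024.

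IVP and Vitro_morula were scanned together on 2 days, one per dye orientation. On the day with the groups in Cy5, 1852 probes differed, and on the day with the groups in Cy3, 5. All 5 were called in the same direction on both days. With the replicate block 3347 probes differed, 1754 higher and 1593 lower, and within the days 6116 and 1025, of which 804 passed on both in the same direction and 1 in opposite directions. The share of higher calls went from 40.2% to 91.2% of 885 calls with median centring and to 21.1% of 19 calls in the authors' value table, and was 62.7% of the 1852 calls in Cy5.

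IVP and Vivo_morula both formed blastocysts in vitro and differed in where they developed up to the morula. No probe was higher in IVP and 8 were lower (limma, adjusted p under 0.05), against 1048 and 969 at an unadjusted p under 0.05. EMBV3_12669 was 9.19-fold lower in IVP (-0.62 ± 0.50 against 2.58 ± 0.13, SD, n = 3; limma adjusted p = 0.0037) and EMBV3_13552 8.03-fold lower (-0.48 ± 0.49 against 2.53 ± 0.20, SD, n = 3; limma adjusted p = 0.0063). These are the 2 probes that led the difference of Vivo_morula from Vitro_morula. With the replicate block 1183 probes differed, 596 higher and 587 lower. With the groups in Cy5, 9 probes passed and in Cy3 15, of which 6 passed in both in the same direction. Blocked fits of the orientations called 141 (31.9% higher) and 3191 (54.8% higher), with 110 in both in the same direction. Leaving out 1 replicate at a time took the 8 calls to between 3, without IVP replicate 2, and 9.

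**Figure D2:**
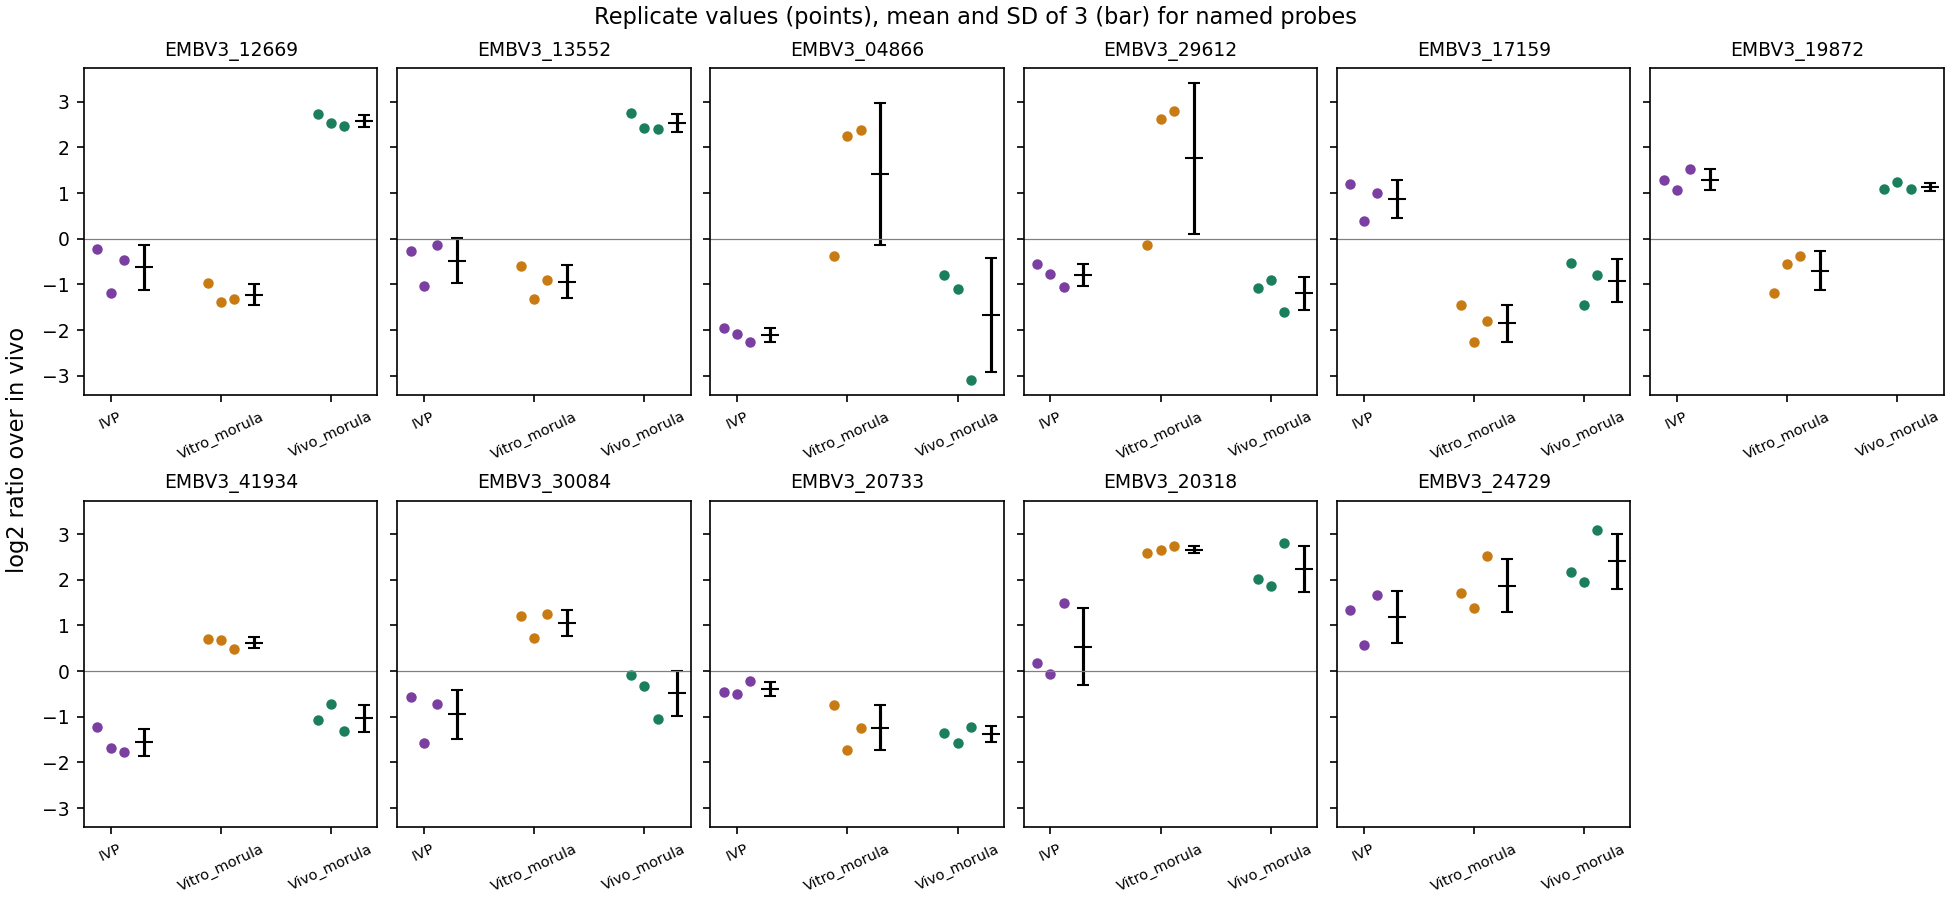
Log2 ratio over in vivo (vertical axis) of 11 probes named for the comparisons between groups and the interaction, by group (horizontal axis). Points are the 3 replicates and bars their mean and SD. EMBV3_12669 stood at 2.58 in Vivo_morula, -1.22 in Vitro_morula and -0.62 in IVP.

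The interaction asks whether the change in IVP equals the sum of the changes in Vitro_morula and Vivo_morula on the log2 scale. It was above 0 at 46 probes and below 0 at 97 (limma, adjusted p under 0.05). EMBV3_20318 rose by 2.65 ± 0.07 in Vitro_morula and 2.23 ± 0.50 in Vivo_morula against 0.54 ± 0.84 in IVP (log2 ratio, SD, n = 3; limma adjusted p = 0.0088). EMBV3_24729 stood at 1.86 ± 0.58, 2.40 ± 0.61 and 1.18 ± 0.56 in the same order (SD, n = 3; limma adjusted p = 0.035). EMBV3_17159 was at -1.85 ± 0.41, -0.92 ± 0.47 and 0.87 ± 0.42 (SD, n = 3; limma adjusted p = 0.0088), and EMBV3_20733 at -1.24 ± 0.49, -1.38 ± 0.17 and -0.39 ± 0.15 (SD, n = 3; limma adjusted p = 0.024). EMBV3_17159 was well above background on 1 of 6 arrays of Vitro_morula, so that its value there is not exact. With each of the 9 replicates left out in turn the count went from 143 to between 12 and 343, and EMBV3_24729 lost its call in 7 of these fits and EMBV3_20733 in 6 (limma adjusted p from 0.061 to 0.099). The 2 dye orientations differed: 132 probes passed in both in the same direction and 129 in opposite directions, and the log2 interactions correlated at 0.31 across probes. The blocked fit called 2899, 1333 above 0 and 1566 below, and in simulated data 16.0% of such calls were unchanged probes. The share above 0 went from 32.2% to 16.2% of 37 calls with the processed signals, and it was 65.1% of 1117 calls with the groups in Cy5 and 26.7% of 581 in Cy3, so the excess below 0 turned with the dye orientation.

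Of the 8207 probes that differed from in vivo in at least 1 group, 862 did so in all 3 in the same direction, 480 higher and 382 lower. With the replicate block, which overstates calls against in vivo, 2734 of 13217 did so. IVP shared 2088 calls of one direction with Vivo_morula and 1645 with Vitro_morula, and Vitro_morula shared 1173 with Vivo_morula. Independent lists of these sizes would share 502, 465 and 581 probes. Opposite calls numbered 19, 52 and 258 in the same order of pairs. Simulated groups with no effect that share the in vivo samples had at most 0 calls in common in 20 simulations. They had at most 2 calls, so this cannot show how far shared samples raise the overlap of longer lists. The blocked fits shared 4993, 4060 and 3321 calls of one direction and had 137, 365 and 1092 opposite ones.

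Another 1198 probes moved the same way in IVP and Vivo_morula and did not pass in Vitro_morula. The direct difference between Vivo_morula and Vitro_morula passed in that direction at 359 of them, and at 787 with the replicate block. Another 776 moved the same way in IVP and Vitro_morula and did not pass in Vivo_morula, with Vitro_morula further from in vivo than Vivo_morula in the direct difference at 144 and, with the block, at 469. Across probes the log2 ratios of IVP correlated at 0.75 with those of Vivo_morula and at 0.58 with those of Vitro_morula, and the latter 2 groups at 0.38. Simulated groups with no effect gave 0.57, 0.56 and 0.57 from the shared in vivo samples alone. The covariances were 0.17, 0.14 and 0.10 against 0.02 simulated for each, and part of the shared calls may come from the shared in vivo samples.

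**Figure D3:**
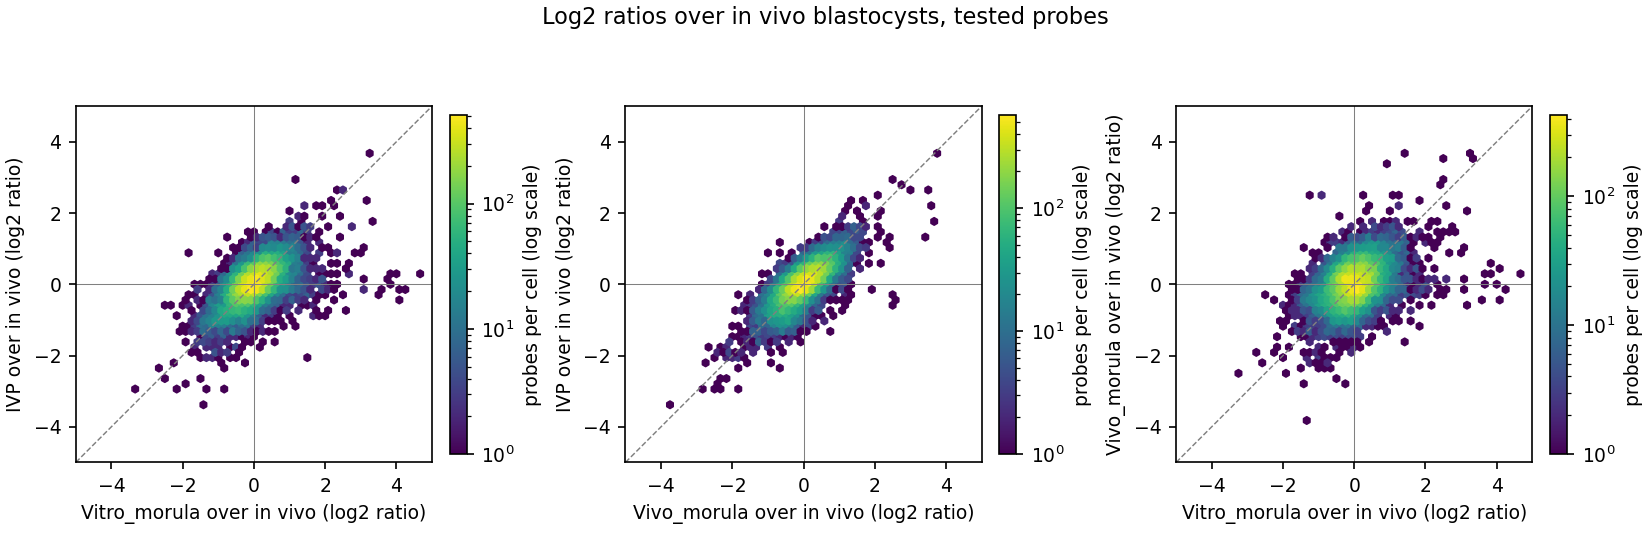
Log2 ratio over in vivo of each tested probe in 2 groups (horizontal and vertical axes), for the 3 pairs of groups, with colour for the number of probes per cell on a log scale and a dashed line where both are equal. The correlations were 0.58 for IVP with Vitro_morula, 0.75 for IVP with Vivo_morula and 0.38 for Vivo_morula with Vitro_morula.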

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

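The tests of array position, of scan day, of slides, of the environment during blastocyst formation and of other splits or signs of the samples were chosen after the results were seen. The remaining ones were written before.

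The interaction passed the threshold at 143 probes, where the IVP change differed from the sum of the other two (limma, test of the difference itself). Leaving out 1 replicate at a time moved this count to between 12 and 343. When the dye orientations were fitted alone, 132 probes passed in both in the same direction and 129 in opposite directions, and orientation goes together with slide and, for IVP and Vitro_morula, with scan day. What the 3 groups share against in vivo and the separate scan day of Vivo_morula also enter this value, so a difference in the effect of the environment is not established. Other signs of the 3 replicate numbers gave at most 0 probes, and 1 of 4 sign patterns, the real one, gave as many; 4 patterns are too few to reach a share under 0.05.

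Of 18 control probes whose names start with DCP, which the comparisons do not use, 16 were well above background in all channels. DCP_1_11 and DCP_20_9 were so in none. Over the 18 probes 88.9% of spot readings were well above background, against 0.56% for the negative controls. What these probes detect is not given in the sources used here. DCP_22_9, chosen after its values were seen, was lower relative to the other probes of its series by log2 ratios over in vivo of -0.77 ± 0.13 (SD, n = 3) in IVP and -0.75 ± 0.14 in Vitro_morula, against -0.28 ± 0.22 in Vivo_morula. No p is given for this division, since the probe was chosen for it. It follows the scan days, and equally the group and the environment before the morula stage.

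Same-numbered replicates of different groups deviated together. An effect of the array's position on the slide that shifts the balance of the dyes would change sign when ratios are turned. Same-numbered arrays of opposite orientation from different groups instead had a median correlation of 0.511, which argues against such a shift. A position effect that stretches or compresses ratios would keep its sign. Same-numbered arrays sat at the same position, so this value cannot exclude it. Embryos of one session shared by the groups would show in the group channels, where the median over 9 pairs was 0.16, below the lowest in vivo pair at 0.66, so this is argued against as the main source. The in vivo channels of same-numbered arrays had a median correlation of 0.725, which is consistent with one in vivo RNA per number, used for all 3 groups. No biological explanation was tested.

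IVP lay nearer to Vivo_morula than to Vitro_morula, with root mean square log2 differences of 0.34 and 0.45 over tested probes. On the 8904 probes well above background in all 36 channels, the ratio of the distance to Vitro_morula over that to Vivo_morula was taken. With both dye orientations averaged it was at least 1.08 for each replicate number. Probes near background therefore do not account for the order in the averages. On the same probes, over all numbers, the ratio was 1.64 in Cy5 and 0.867 in Cy3, and an effect of dim arrays as a whole was not tested. A scan day shared by IVP and Vitro_morula would work against IVP lying nearer to Vivo_morula rather than produce it. IVP was nearer to Vivo_morula in 4 of 6 combinations of number and orientation, 3 of 3 in Cy5 and 1 of 3 in Cy3. How far scan day shaped these distances stays open, as does an effect of the slides, one per group and orientation. The environment during blastocyst formation as the only factor needs under 5% as many probes past the threshold in Vitro_morula as in Vivo_morula. The share was 93.4%, and it went from 26.2% to 285% with 1 replicate left out at a time. Unsteady as it is, the share stayed above 5% in all 9 of these fits. Calls against in vivo also hold anything common to the 3 groups, such as an offset of the in vivo RNA or handling. The share therefore cannot decide whether this environment was the only factor. Staging by fixed time, which IVP and Vivo_morula share, was not tested.

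A total of 862 probes moved the same way in all 3 groups. If the in vivo RNA alone were set apart by a fixed offset, about 5% of these would differ between Vivo_morula and Vitro_morula at an unadjusted p under 0.05, and 28.5% did with the replicate block and 14.3% without it; over all tested probes the shares were 50.6% and 32.8%, and the choice of the 862 itself lowers theirs. Probes were also simulated with one common offset and chosen in the same way, a comparison added after the result was seen. They gave at most 5.51% and 1.33% in 20 simulations, which chose 3000 probes on average and held no other difference between the groups. The values show that Vivo_morula and Vitro_morula differ at part of the 862, as they do at many other probes. Since scan day goes with Vivo_morula, they cannot decide whether an offset moved the 862. Handling outside the donor, common to the 3 groups, cannot be told apart from such an offset, since the series has 0 groups of in vivo embryos that were handled and not moved.

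The counts of IVP, Vitro_morula and Vivo_morula against in vivo, 3674, 4283 and 4586, stood against at most 0 under other signs of the replicates, with 1 of 4 patterns as large in each. In the differences between Vivo_morula and Vitro_morula, IVP and Vitro_morula, and IVP and Vivo_morula, with 2341, 97 and 8 probes, 1 of 10 splits was as large in each and the highest other gave 0, also among the 4 splits that part all 3 pairs. These designs have too few patterns or splits for a share under 0.05.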

How the results depend on the processing

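All 26 named results kept their direction under every alternative that gave a value, and 76 of the values were no longer past the threshold, against 630 that were. No count moved by over 1.5 times with no background subtraction, Aquantile (which leaves ratios as they are), quantile normalization of both channels, the strict filter or flagged spots kept. Elsewhere these counts of probes moved by more, and the cause was not tested. Blocked counts against in vivo overstate the differences, as the simulated arrays showed. Processed signals centred on the median gave 2611 for Vitro_morula against in vivo, 19 for Vivo_morula against Vitro_morula, 2 for IVP against Vitro_morula, 14 for IVP against Vivo_morula and 37 for the interaction. Median centring gave 7041 for IVP against in vivo, 885 for IVP against Vitro_morula, 5 for IVP against Vivo_morula and 19 for the interaction. The authors' table gave 19 for IVP against Vitro_morula. Without a filter on dim probes the counts were 5563 for IVP against in vivo, 12610 for Vitro_morula against in vivo, 16564 for Vivo_morula against in vivo, 18131 for Vivo_morula against Vitro_morula and 8270 for IVP against Vitro_morula. Fitting 18 arrays with the replicate as a random effect gave 810 for IVP against Vitro_morula, 83 for IVP against Vivo_morula and 885 for the interaction. With slide as a random effect, where dye-swapped arrays count as separate, they were 8011 for IVP against in vivo, 8769 for Vitro_morula against in vivo, 8875 for Vivo_morula against in vivo, 7535 for Vivo_morula against Vitro_morula, 4296 for IVP against Vitro_morula, 1877 for IVP against Vivo_morula and 3504 for the interaction. Arrays with the group in Cy5 gave 5961 for IVP against in vivo, 1852 for IVP against Vitro_morula and 1117 for the interaction. The replicate block on Cy5 arrays alone, added after seeing the data, gave 9402 for IVP against in vivo, 9162 for Vitro_morula against in vivo, 9584 for Vivo_morula against in vivo, 6562 for Vivo_morula against Vitro_morula, 6116 for IVP against Vitro_morula, 141 for IVP against Vivo_morula and 4879 for the interaction. Arrays with the group in Cy3 gave 876 for Vivo_morula against Vitro_morula, 5 for IVP against Vitro_morula, 15 for IVP against Vivo_morula and 581 for the interaction. The replicate block on Cy3 arrays alone, also added, gave 8546 for IVP against in vivo, 8388 for Vitro_morula against in vivo, 8222 for Vivo_morula against in vivo, 4816 for Vivo_morula against Vitro_morula, 1025 for IVP against Vitro_morula, 3191 for IVP against Vivo_morula and 3987 for the interaction. The replicate block gave 7458 for IVP against in vivo, 8213 for Vitro_morula against in vivo, 8432 for Vivo_morula against in vivo, 6993 for Vivo_morula against Vitro_morula, 3347 for IVP against Vitro_morula, 1183 for IVP against Vivo_morula, 2899 for the interaction, 4060 for shared calls of IVP and Vitro_morula, 4993 for shared calls of IVP and Vivo_morula and 3321 for shared calls of Vitro_morula and Vivo_morula. Fits of the compared groups alone gave 1158 for IVP against in vivo, 2586 for Vitro_morula against in vivo and 0 for IVP against Vitro_morula. Separate channels with 3 in vivo samples gave 3044 for Vivo_morula against in vivo, 3530 for Vivo_morula against Vitro_morula, 4371 for IVP against Vitro_morula, 260 for IVP against Vivo_morula and 1642 for the interaction. An adjusted p with a 2-fold change gave 697 for IVP against in vivo, 846 for Vitro_morula against in vivo, 739 for Vivo_morula against in vivo and 689 for Vivo_morula against Vitro_morula. An unadjusted p with a 2-fold change gave 730 for IVP against in vivo, 895 for Vitro_morula against in vivo, 787 for Vivo_morula against in vivo, 951 for Vivo_morula against Vitro_morula, 470 for IVP against Vitro_morula, 124 for IVP against Vivo_morula, 892 for the interaction, 284 for shared calls of IVP and Vitro_morula, 319 for shared calls of IVP and Vivo_morula and 187 for shared calls of Vitro_morula and Vivo_morula. Keeping only probes well above background in all 36 channels, added after seeing the data, gave 2367 for IVP against in vivo, 2445 for Vitro_morula against in vivo, 2706 for Vivo_morula against in vivo, 996 for Vivo_morula against Vitro_morula and 5 for IVP against Vivo_morula. Leaving out 1 replicate at a time gave 1228 to 3505 for IVP against in vivo, 1152 to 4612 for Vitro_morula against in vivo, 1399 to 4908 for Vivo_morula against in vivo, 4 to 2585 for Vivo_morula against Vitro_morula, 0 to 339 for IVP against Vitro_morula, 3 to 9 for IVP against Vivo_morula, 12 to 343 for the interaction. Gene lists and gene-level means were not run, since the files used here name no genes.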

Other observations

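Both observations were chosen after the values were seen.

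In Vitro_morula 24 probes had log2 ratios over in vivo above 3 in replicates 2 and 3 and below 1 in replicate 1. Their medians were 4.17 and 5.20 in replicates 2 and 3, -0.08 in replicate 1 and -0.01 in the 6 replicates of the other groups. The same rule, set after the values were seen, found 0 probes for any other choice of replicate in the 3 groups. EMBV3_04607 and EMBV3_06488 are among the probes with this division, and the identity of the 24 probes was not analysed here.

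The DCP control probes differed between replicates of a group by more than between groups. The median log2 ratio over in vivo of the 16 detected ones was 0.40, -0.24 and -0.97 in the 3 IVP replicates. It was -0.20, -0.39 and -0.60 in Vitro_morula and -0.08, 0.16 and -0.40 in Vivo_morula. Replicate 3 was the lowest in each group. By number, Vivo_morula lay above Vitro_morula each time, while IVP lay above Vivo_morula for number 1 and below it for numbers 2 and 3.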
